A study of Homo sapiens with 12 samples.

How the data were processed

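The deposited values are raw gene counts, which per the submitters' processing notes were made after alignment with STAR 2.6.0a and the genome build GRCh38 (the notes list both without saying what each was used for). The counting tool, the gene annotation and the strand setting are not given in the sources used here. RNA was taken with a Norgen total RNA kit and libraries were made with a TruSeq kit, per the labels. Per the series design, 100K cells were plated in duplicate wells, 24 hours before some wells moved to 0.5% oxygen, and cells were harvested at 72 hours. The design does not say whether the 72 hours run from plating or from the move.

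The table holds 43809 gene symbols in 12 libraries, and 16366 of them have no count in any library. Of the symbols, 4812 carry a suffix that marks a further copy of a gene and were kept apart. They hold 0.0278 to 0.0334% of the counts of a library, and a gene with such copies, or with near-identical relatives, is called uncertain in the text. Genes are named by symbol, and coordinates are those of GRCh38.

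The comparisons, the gene lists, the main test and most alternatives were fixed before the data were examined. The comparisons are hypoxia against normoxia within each guide, each targeting guide against sgCTRL within each oxygen level, and for each targeting guide the interaction, which is the difference between its response to hypoxia and that of sgCTRL. The comparison of the 2 targeting guides with each other, the use of the fit without sgITPR3 hypoxia replicate 1 beside the counts, the voom fit with library weights and the offset for transcript length were added after the data had been seen.

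All 12 libraries entered a single edgeR quasi-likelihood fit with 1 coefficient per group, normalisation by the trimmed mean of M values, the filterByExpr rule (minimum count 10, minimum total 15) and robust estimation of the spread. The fit tested 16153 genes with 6 residual degrees of freedom and a median prior of 3.18 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. Fold changes used a prior count of 0.125 and log2 CPM a prior count of 2. With 2 libraries against 2, the smallest exact two-sided permutation p is 0.333, so no rank or permutation test of a single gene could pass.

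Genes named in the text are ITPR3 and RELB, then the genes of largest change each way with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups, and up to 4 members of a list with the smallest p. A gene with few counts in a group is given as a depth-corrected ratio of summed counts with a 95% interval that covers counting error only.

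The 33 gene lists were written from general knowledge of each pathway and tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The test was repeated with a correlation estimated from the data. The lists include markers of other cell types. Counts of called members are given over all genes and also adjusted over the list alone. The size of the response was tested with limma fry. The correlation and covariance of the guides were set against those of 20 simulated data sets in which the guides had no effect and the sgCTRL libraries were shared. After the data had been seen, edgeR was also fitted with a coefficient for each sgCTRL library, and each guide was compared with a different one, both ways round, with the spread of a lone library taken from the other groups. In a further simulation of known changes, the fit for hypoxia in sgCTRL recovered 46.3% of 67 genes changed 2-fold and 87.9% of 66 changed 4-fold. That simulation changed far fewer genes than were called for hypoxia in the data. Its spread came from the fit of all 12 libraries, so its rates need not hold for the real comparisons.

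Transcript lengths are those of the longest GENCODE 29 transcript. The alternatives used edgeR 4.0.16, limma 3.58.1 (voom) and DESeq2 1.42.0 under R 4.3.3, and figures used matplotlib 3.10.9.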

Results

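RNA was sequenced from SW480, a cell line grown from a human colorectal cancer, after CRISPR editing with 1 of 3 guides. The guide sgCTRL was the control, sgITPR3 was aimed at ITPR3, an inositol trisphosphate receptor that releases calcium from the endoplasmic reticulum, and sgRELB was aimed at RELB, a subunit of the transcription factor NF-kB. Cells with each guide were kept in normoxia or held at 0.5% oxygen (hypoxia) and harvested at 72 hours, which gave 6 groups of 2 libraries. The total of gene counts (M, 1e6 counts) was 22.06 and 17.36 M for sgCTRL in normoxia, 22.26 and 26.82 M for sgITPR3 in normoxia, and 24.61 and 27.15 M for sgRELB in normoxia. In hypoxia the totals were 23.25 and 23.09 M for sgCTRL, 15.02 and 26.07 M for sgITPR3, and 25.13 and 25.43 M for sgRELB. Levels are normalised counts per M (CPM) as mean ± SD over 2 libraries, and changes are log2 fold changes ± an approximate standard error. That error is the size of the log2 fold change divided by the square root of the test's F statistic. It is not estimated by the model itself and is less reliable for genes with few counts. Adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named. The p-values measure only the spread between these libraries, which came from duplicate wells, and that spread may be technical.

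ITPR3 RNA was lower in both sgITPR3 groups and RELB RNA was lower in both sgRELB groups, and each targeted gene was still transcribed. ITPR3 (chromosome 6, 33621322 to 33696562, GRCh38) stood at 455 ± 4.59 CPM in sgCTRL in normoxia and at 178 ± 2.40 CPM in sgITPR3, a change of -1.35 ± 0.28 (edgeR adjusted p = 0.0159). The single libraries had 452 and 458 CPM in sgCTRL and 176 and 180 CPM in sgITPR3. In hypoxia ITPR3 had 465 and 442 CPM in the sgCTRL libraries and 77.5 and 168 CPM in the sgITPR3 libraries, a change of -1.88 ± 0.28 (edgeR adjusted p = 0.00307). RELB (chromosome 19, 45001464 to 45038192) had 13.8 and 11.7 CPM in the sgCTRL libraries in normoxia and 6.80 and 6.80 CPM in the sgRELB libraries, a change of -0.91 ± 0.18 (edgeR adjusted p = 0.00913). In hypoxia RELB had 18.4 and 18.6 CPM with sgCTRL and 5.39 and 5.78 CPM with sgRELB, a change of -1.72 ± 0.18 (edgeR adjusted p = 2.74e-04). RELB rose by 0.54 ± 0.17 in hypoxia in sgCTRL cells (edgeR adjusted p = 0.0397), and it was at 14.6 and 14.2 CPM in normoxia and 19.99 and 13.57 CPM in hypoxia with sgITPR3. ITPR3 with sgRELB was at 302 and 341 CPM in normoxia and 301 and 319 CPM in hypoxia, which did not pass the test against sgCTRL (-0.50 ± 0.27, edgeR adjusted p = 0.269; -0.55 ± 0.27, 0.211). Without sgITPR3 hypoxia replicate 1, a library treated below, ITPR3 was called lower with sgRELB in normoxia (-0.51, edgeR adjusted p = 3.48e-14) and hypoxia (-0.53, 4.84e-15). RELB in sgITPR3 vs sgCTRL in hypoxia did not pass (-0.15 ± 0.17, edgeR adjusted p = 0.540). Without that library the change was -0.43, which rests on 1 sgITPR3 library at 13.57 CPM. The library left out, at 19.99 CPM, lay above both sgCTRL libraries (18.4 and 18.6 CPM). The 2 sgITPR3 libraries thus lay on opposite sides of sgCTRL. The difference in the RELB response to hypoxia from that in sgCTRL was -0.32 (edgeR adjusted p = 0.507) with sgITPR3 and -0.82 (0.249) with sgRELB. Without sgITPR3 hypoxia replicate 1 it was -0.58 with sgITPR3, again resting on the 1 hypoxia library left, and -0.78 with sgRELB. The call for ITPR3 in sgITPR3 vs sgCTRL in normoxia was lost when any of its 4 libraries was left out: the adjusted p was 0.0842 or 0.0869 without sgCTRL replicate 1 or 2, and 0.120 or 0.107 without sgITPR3 replicate 1 or 2. The call for RELB in sgRELB vs sgCTRL in normoxia was lost without sgCTRL replicate 1 (0.0948) or sgRELB replicate 1 or 2 (0.0740, 0.0744). The call for RELB in hypoxia vs normoxia in sgCTRL was lost without any library other than those of sgITPR3 in hypoxia (0.0667 to 0.256). The fits in which these calls were lost all kept sgITPR3 hypoxia replicate 1, which widened the spread shared by all groups. Without that library ITPR3 changed by -1.37 in normoxia and -1.42 in hypoxia in sgITPR3 vs sgCTRL. RELB changed by -0.92 and -1.705 in sgRELB vs sgCTRL. In each of these comparisons the libraries of the 2 groups did not overlap in CPM. An RNA level does not measure how much protein an edited gene makes.

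**Figure D1:**
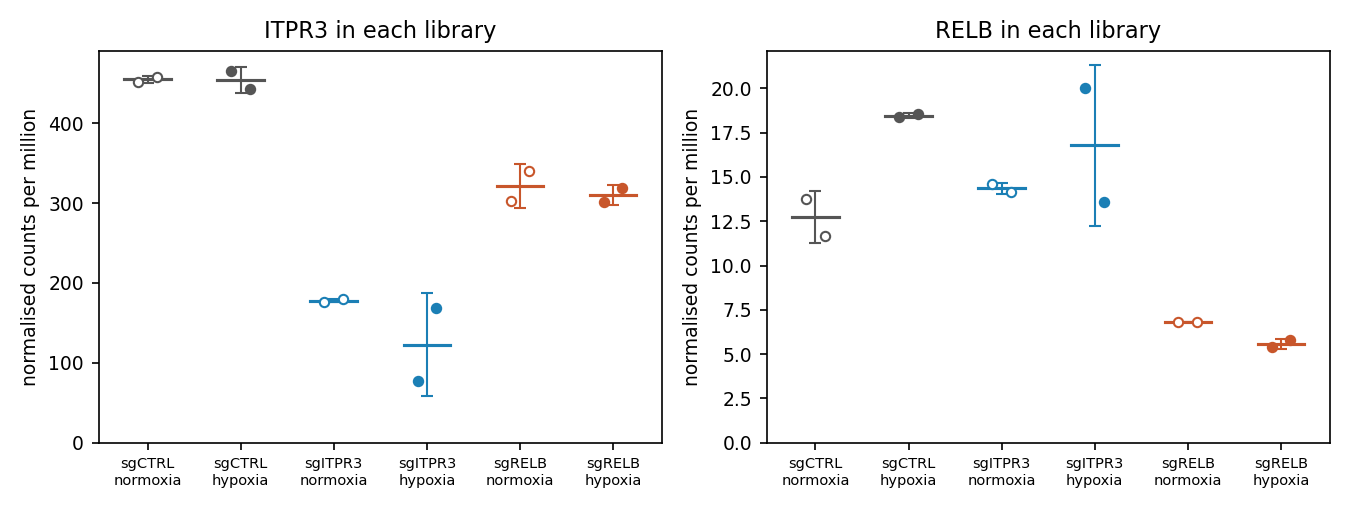
ITPR3 and RELB in normalised counts per M in the 6 groups, with each point a library, each line the mean and each bar the SD (n = 2). ITPR3 lies at 77.5 to 180 in the 4 sgITPR3 libraries and at 301 or more in the other 8, and RELB lies at 5.39 to 6.80 in the 4 sgRELB libraries and at 11.7 or more elsewhere.

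The 2 libraries of sgITPR3 in hypoxia differed from each other. The SD across genes of the log2 difference between the 2 libraries of a group was 0.712 for sgITPR3 in hypoxia and 0.0874 to 0.113 in the other 5 groups, and the chi-square per gene was 126 against 1.82 to 3.27. In that pair, the median log2 difference, replicate 1 minus replicate 2, was 0.86 in the tenth of genes with the shortest transcripts (median 1310 bases) and -0.83 in the tenth with the longest (median 9750 bases). In the other 5 pairs every such median lay between -0.064 and 0.047. On the third principal component (18.9% of the variance) replicate 1 lay at -78.6 and the other 11 libraries between -16.1 and 30.6, with replicate 2 at 12.8, so replicate 1 is the library that stands apart there. Because all groups share 1 estimate of the spread, the difference widened it for every comparison: the common dispersion was 0.0195 with replicate 1 and 0.00106 without it. Leaving out replicate 2 instead also raised the counts, to 10535 genes for hypoxia in sgITPR3 against 7892 without replicate 1, so the counts alone do not tell which library is the odd one. The numbers of called genes and of shared calls are therefore given with those of a refit without replicate 1. That pairing was chosen after the data had been seen. The refit tested 16661 genes with 5 residual degrees of freedom. It left 1 library of sgITPR3 in hypoxia, so the spread of that group was taken wholly from the other groups. Its calls that involve sgITPR3 in hypoxia, the sgITPR3 interaction included, are therefore not replicated.

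**Figure D2:**
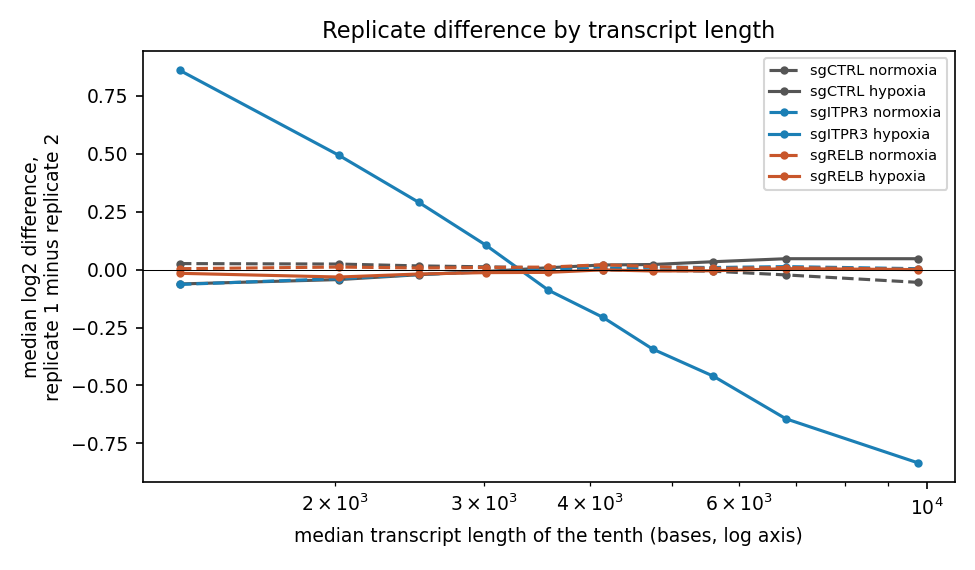
Median log2 difference between replicate 1 and replicate 2 (vertical axis) in 10 groups of genes ordered by transcript length in bases (horizontal axis, log scale), with 1 line per group of libraries. The line of sgITPR3 in hypoxia falls from 0.86 to -0.83, and the other 5 lines stay between -0.064 and 0.047.

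The first question was which genes low oxygen changes in control cells. CA9, a carbonic anhydrase of the cell surface that the hypoxia-inducible factors (HIF) switch on, rose in sgCTRL cells from 1.27 ± 0.163 to 45.0 ± 2.42 CPM (5.14 ± 0.29, edgeR adjusted p = 8.34e-06). IGFBP3, which binds insulin-like growth factors, rose from 52.3 ± 3.66 to 2147 ± 31.4 CPM (5.36 ± 0.13, edgeR adjusted p = 1.45e-07). EHD2, a membrane-shaping protein of caveolae, rose by 6.21 ± 0.21, SIGLEC6, a sialic acid receptor, by 5.88 ± 0.35, SLC6A12, a betaine and GABA transporter, by 5.72 ± 0.40, and KISS1, the precursor of kisspeptin, by 5.33 ± 0.49. The cytokine gene CSF2 had 334 counts in hypoxia and 2 in normoxia, a depth-corrected ratio of 138 with a 95% counting interval of 38 to 1150. PRSS35, a serine protease gene, had 330 counts against 4, a ratio of 68.3 (26.4 to 252). DKK4, a secreted inhibitor of Wnt signalling, fell from 652 ± 38.2 to 49.4 ± 5.94 CPM (-3.72 ± 0.14, edgeR adjusted p = 8.52e-07). KANK4 (-3.13 ± 0.25), the calcium channel gene CACNA1E (-2.98 ± 0.22), TEX15 (-2.92 ± 0.31), DDN (-2.62 ± 0.17) and the hyaluronan synthase HAS3 (-2.55 ± 0.17) also fell. In all, 4882 of 16153 genes were called, 2627 higher and 2255 lower, and 1864 of them changed at least 2-fold. The count was 10036 without sgITPR3 hypoxia replicate 1 (4805 higher, 5231 lower), and these included 4881 of the 4882.

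Hypoxia targets led the gene lists in sgCTRL cells, followed by genes of the extracellular matrix and of NF-kB signalling, while genes of DNA replication and ribosome production fell. Of 34 hypoxia-inducible targets, 29 rose and 1 fell, with the same counts adjusted over the list alone (median 1.68, camera adjusted p = 3.96e-43), led by BNIP3L (2.70 ± 0.09), EGLN3 (3.15 ± 0.11) and STC2 (2.78 ± 0.11). Collagen-modifying enzymes rose (7 of 12, or 9 adjusted over the list alone; median 0.84, camera adjusted p = 1.8e-07), as did mesenchymal genes (18 of 25, the same count adjusted over the list alone; 1.47, 5.8e-14), with CCN2 at 2.14 ± 0.12 and MMP2 at 2.54 ± 0.16. Fibroblast and endothelial markers moved the same way (5 of 7, or 6 adjusted over the list alone; camera adjusted p = 9.45e-04, or 0.13 with an estimated correlation): COL1A1 rose from 4.41 to 20.2 CPM and PDGFRB, which is also in the mesenchymal list, from 0.588 to 2.96 CPM. NF-kB target genes rose (21 of 26, the same count adjusted over the list alone; median 0.89, camera adjusted p = 3.7e-09), with the inhibitor of apoptosis BIRC3 at 3.72 ± 0.32 and TNFAIP3 at 3.23 ± 0.31. Ribosome biogenesis fell (21 of 28, or 23 adjusted over the list alone; -0.86, camera adjusted p = 2.79e-11), as did DNA replication (27 of 36, or 30; -0.70, 7.46e-12), with MCM10 at -1.28 ± 0.10. These lists, apart from the fibroblast and endothelial markers, kept their calls when the correlation between genes was estimated (adjusted p of 1.16e-04 for hypoxia targets, 0.00743, 0.00249 and 0.00367 for the next lists, 0.00249 for ribosome biogenesis and 0.0103 for DNA replication).

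Further lists passed the preset test in sgCTRL cells and lost the call with an estimated correlation, whose adjusted p follows each. Genes of the glycolysis list rose (13 of 18, also adjusted over the list alone; median 0.73, 0.0771), led by PDK1 (1.94 ± 0.13). PDK1 is a pyruvate dehydrogenase kinase rather than an enzyme of glycolysis. Both PDK1 and LDHA are also in the list of hypoxia-inducible targets. Calcium- and serum-responsive immediate genes rose (12 of 24, also adjusted over the list alone; 0.43, 0.0771), led by JUN (1.68 ± 0.13), and so did genes of endoplasmic reticulum stress (9 of 22, or 10 adjusted over the list alone; 0.26, 0.0771), led by DNAJB9 (1.82 ± 0.10). Colon epithelium differentiation genes rose on balance (5 of 14 higher, or 7 adjusted over the list alone; 0.57, 0.0943), with CDH1 at 1.35 ± 0.15, although the transcription factor CDX2 fell (-1.28 ± 0.17). HIF subunits and regulators (0.17, 0.317), the NF-kB family and its kinases (0.039, 0.173) and the ATF4 and amino acid response (0.36, 0.362) had higher medians. Mitosis genes fell (15 of 32, or 19 adjusted over the list alone; -0.46, 0.0771), as did heat shock genes (8 of 13, or 10; -0.70, 0.133), replication-dependent histones (5 of 10, also adjusted over the list alone; -0.60, 0.0943), cholesterol synthesis (10 of 24, or 11; -0.30, 0.0771) and the nuclear-encoded respiratory chain (9 of 37, or 8; -0.42, 0.617). Pyrimidine synthesis and gluconeogenesis (-0.56, 0.0851), fatty acid synthesis (-0.48, 0.526) and cytosolic ribosomal proteins (-0.34, 0.748) had lower medians. Without sgITPR3 hypoxia replicate 1 the preset test no longer called the histones (camera adjusted p = 0.056), the NF-kB family (0.0623) or markers of hepatic, kidney and neural lines (0.0259 with it, 0.0761 without). Histone and ribosomal protein genes share reads with near-identical copies, so their values are uncertain.

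Low oxygen was also compared within the cells of each other guide, to ask what the response looks like with ITPR3 or RELB edited. CA9 rose by 6.32 ± 0.31 in sgITPR3 (edgeR adjusted p = 8.33e-06) and by 6.14 ± 0.35 in sgRELB (1.62e-05), and SIGLEC6 by 5.66 ± 0.36 and 5.57 ± 0.35. ANGPTL4, an inhibitor of lipoprotein lipase, rose with sgITPR3 (601 counts against 15, a ratio of 47.7 with a counting interval of 28.7 to 85.7), and the hormone gene STC1 rose with sgRELB (429 counts against 6, 70.1, 31.9 to 192), as did PKHD1 (390 counts against 7, 54.6, 26.2 to 137). DKK4 fell in both (-2.86 ± 0.14 and -4.46 ± 0.19), as did TEX15 (-2.44 ± 0.34 and -2.63 ± 0.33) and CD22 (-2.25 ± 0.19 and -2.18 ± 0.18), and SH2D2A fell with sgRELB (-2.40 ± 0.32). With sgITPR3, 3527 genes were called (1847 higher, 1680 lower; 1198 at least 2-fold), and without sgITPR3 hypoxia replicate 1 there were 7892 (3788 higher, 4104 lower), 3445 of them shared. With sgRELB, 3438 genes were called (1895 higher, 1543 lower; 1182 at least 2-fold), and 9335 without that library (4616 higher, 4719 lower), 3436 of them shared. Between sgCTRL and sgITPR3, 1296 higher and 1139 lower calls were shared, where independent lists would share 300 and 235, and 13 calls were opposite; without the library the numbers were 2971 and 3523 (1090 and 1290 for independent lists, 145 opposite). Between sgCTRL and sgRELB, 1419 higher and 1243 lower calls were shared (308 and 215 for independent lists, 18 opposite), or 3358 and 3901 without the library (1330 and 1480, 217 opposite). All 3 populations shared 1045 higher and 846 lower calls, or 2715 and 3247 without the library. The 3 responses share no library, and their log2 fold changes correlated across genes, which are not independent replicates, with Pearson r of 0.688, 0.763 and, between the 2 edited populations, 0.739.

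Hypoxia-inducible targets, collagen-modifying enzymes, mesenchymal genes and ribosome biogenesis kept their calls with an estimated correlation in all 3 populations, and NF-kB targets kept it in sgCTRL alone. This holds for the fit with all libraries. Without sgITPR3 hypoxia replicate 1 the lists kept there were kept again, and further lists were kept in each population. A call lost with an estimated correlation in the edited populations may therefore rest on that library. Of the 34 hypoxia-inducible targets, 29 rose with sgITPR3 (31 adjusted over the list alone; median 1.57) and 29 with sgRELB (29; 1.58), and the calls held with an estimated correlation (5.43e-05 and 5.11e-05). Glycolysis enzymes rose in 16 of 18 and 13 of 18 (16 and 16 adjusted over the list alone; estimated-correlation p of 0.0104 and 0.0174), collagen-modifying enzymes in 8 of 12 each (9 and 8; 0.00802 and 0.00495) and mesenchymal genes in 16 and 17 of 25 (16 and 19; 0.00664 and 0.00483). Fibroblast and endothelial markers rose beside them in 4 of 7 with each guide (5 and 4 adjusted over the list alone; 0.264 and 0.171 with an estimated correlation). Ribosome biogenesis fell in 17 and 20 of 28 (23 and 24 adjusted over the list alone; 0.00367 and 0.00103). DNA replication fell in 13 and 19 of 36 (15 and 21), with an estimated-correlation p of 0.15 for sgITPR3 and 0.0347 for sgRELB. NF-kB target genes rose in 10 of 26 with sgITPR3 (10 adjusted over the list alone; median 0.57, camera adjusted p = 0.0155, or 0.101 with an estimated correlation). With sgRELB, 5 rose and the list did not pass. Markers of hepatic, kidney and neural lines were called higher with sgITPR3 (0.41, camera adjusted p = 0.0394, or 0.228 with an estimated correlation) and not without sgITPR3 hypoxia replicate 1 (0.201). Metallothioneins and oxidative stress genes were called lower with sgRELB alone (5 of 23, 5 adjusted over the list alone; -0.30, camera adjusted p = 0.0281, or 0.542 with an estimated correlation), led by HMOX1 (-1.02 ± 0.16); with sgITPR3 that list passed only without sgITPR3 hypoxia replicate 1 (camera adjusted p = 0.00121). Cytosolic ribosomal proteins had a median of 0.53 with sgITPR3 and of -0.19 without that library, so their direction rests on it.

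**Figure D3:**
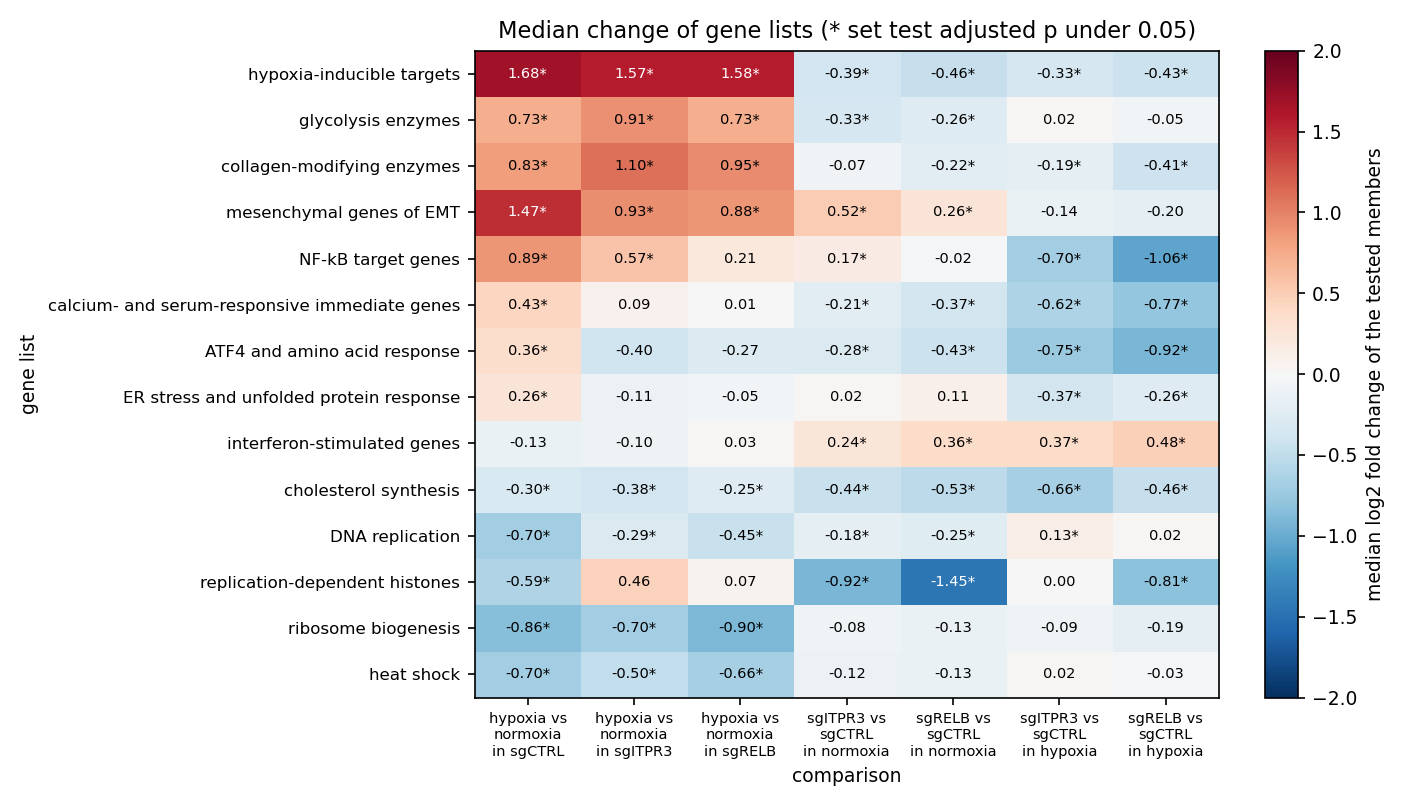
Median log2 fold change of 14 gene lists (vertical) in 7 comparisons (horizontal) as a colour scale, with * where the set test passed at an adjusted p under 0.05. Hypoxia-inducible targets stand at 1.68, 1.57 and 1.58 in the 3 hypoxia columns, and NF-kB target genes at -0.70 and -1.06 in the 2 columns of guides in hypoxia.

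Whether the response differed in size was measured on genes called in the third population, so that no library chose its own genes. Over the 3438 genes called with sgRELB, the median response was 0.797 in sgCTRL and 0.633 in sgITPR3, and 67% of genes responded less with sgITPR3. The median difference was -0.18 (quartiles -0.47 and 0.094). The model-based limma fry test gave p = 0.00218, which is not an exact permutation p. Over the 3527 genes called with sgITPR3, the median response was 0.73 in sgCTRL and 0.611 in sgRELB, a median difference of -0.11 that did not pass (limma fry, model-based and not exact, p = 0.144). Without sgITPR3 hypoxia replicate 1 the differences were -0.087 (limma fry, not exact, p = 3.48e-04) and -0.07 (3.97e-04), over other and longer sets of genes, so both passed.

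The effect of the ITPR3 guide in normoxia was the next comparison. CDH11, a mesenchymal cadherin, rose from 1.03 ± 0.166 CPM in sgCTRL to 30.1 ± 3.00 CPM in sgITPR3 (4.85 ± 0.34, edgeR adjusted p = 1.35e-04). RPS6KA6, a kinase gene of chromosome X, had 228 counts against 3, a ratio of 57.5 (counting interval 19.4 to 281). The growth factor receptor PDGFRB (3.39 ± 0.34), the protease CTSS (3.23 ± 0.31) and VIL1, a protein of intestinal microvilli (2.95 ± 0.19), rose too. IGFBP5 had 82 counts against 4 (ratio 15.5, 5.83 to 58.3) and ALPK2 had 91 against 4 (17.2, 6.49 to 64.5), and FAM131B rose by 4.09 ± 0.37, uncertain because copies of it are counted apart. DKK4 fell from 652 ± 38.2 to 40.7 ± 3.34 CPM (-4.00 ± 0.14, edgeR adjusted p = 4.48e-06). AFAP1-AS1 fell by 3.86 on the log2 scale, uncertain because an antisense gene cannot be told from its partner without strand, and COBLL1 (-2.85 ± 0.18), the ephrin EFNA5 (-2.78 ± 0.24) and SORCS2 (-2.72 ± 0.24) fell as well. In all, 1589 genes were called, 982 higher (61.8%) and 607 lower, 662 of them at least 2-fold. The fit without sgITPR3 hypoxia replicate 1 called 7391 (3367 higher, 45.6%, and 4024 lower), which included the 1589.

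With sgITPR3 in normoxia, genes of cholesterol synthesis, hypoxia targets and histones fell and mesenchymal genes rose. Cholesterol synthesis fell in 12 of 24 genes (13 adjusted over the list alone; median -0.44, camera adjusted p = 3.5e-11, or 0.00937 with an estimated correlation). Hypoxia-inducible targets fell in 11 of 34 (16; -0.39, 1.12e-07, or 0.00937), led by NDRG1 (-1.24 ± 0.10). Histones fell in 6 of 10 (6; -0.92, 6.73e-08, or 0.00937), and mesenchymal genes rose in 8 of 25 (9; 0.52, 7.77e-07, or 0.0127), with MMP2 at 2.06 ± 0.16. Fibroblast and endothelial markers rose in 2 of 7 (2; camera adjusted p = 0.0189, or 0.267 with an estimated correlation): COL1A1 stood at 20.4 CPM and PDGFRB at 6.21 CPM. Interferon-stimulated genes rose in 6 of 29 (6; 0.24, 0.011, or 0.106 with an estimated correlation), led by MX1 (1.34 ± 0.15). Antigen presentation genes, uncertain because their locus has alternate copies, had a median of 0.24 (0.0222, or 0.259). The ATF4 response (-0.28, 0.00203, or 0.22), glycolysis (-0.33, 4.04e-04, or 0.144) and DNA replication (-0.18, 0.00148, or 0.144) had lower medians. Calcium channels, pumps and sensors, a mixed list that includes ITPR3, passed in none of the 9 comparisons (33 genes, medians -0.11 to 0.033, smallest camera adjusted p = 0.629). The fibroblast and endothelial markers no longer passed without sgITPR3 hypoxia replicate 1 (0.0684), nor did the NF-kB targets, which had a higher median (0.17, camera adjusted p = 0.036, or 0.144 with an estimated correlation; 0.113 without the library). With an estimated correlation the mesenchymal list lost its call without it (0.0682), and the cholesterol, hypoxia and histone lists kept theirs (0.0375 for each).

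The effect of the RELB guide in normoxia was larger in number. CDH11 rose to 46.0 ± 2.14 CPM (5.47 ± 0.34, edgeR adjusted p = 2.73e-05) and RPS6KA6 had 265 counts against 3 (63.8, counting interval 21.6 to 312). ATP10A, a lipid flippase gene, had 103 counts against 4 (18.6, 7.05 to 69.6), IGFBP5 had 52 against 4 (9.4, 3.46 to 35.8), and the complement protease C1S (3.27 ± 0.21) and the transcription factor CUX2 (3.18 ± 0.31) rose. DKK4 fell to 11.7 CPM (-5.80 ± 0.15, edgeR adjusted p = 3.56e-07). AFAP1-AS1, uncertain for its antisense place, had 5 counts against 332 (0.0109, 0.00351 to 0.0257), and SORCS2 (-4.66 ± 0.29), VAT1L (-4.58 ± 0.16), the prohormone convertase PCSK1 (-4.16 ± 0.30) and the cytokine IL24 (-3.69 ± 0.27) fell. There were 2438 calls (1319 higher, 1119 lower; 951 at least 2-fold), and 8195 without sgITPR3 hypoxia replicate 1 (3892 higher, 4303 lower), which included the 2438. Cholesterol synthesis fell in 12 of 24 genes (15 adjusted over the list alone; median -0.53, camera adjusted p = 6.05e-10, or 0.00888 with an estimated correlation), led by INSIG1 (-1.16 ± 0.09). Histones fell in 6 of 10 (6; -1.45, 2.17e-11, or 0.00888), and hypoxia-inducible targets in 14 of 34 (16; -0.46, 8.96e-07, or 0.00902). Interferon-stimulated genes rose in 7 of 29 (9; 0.36, 0.00728, or 0.0922), and mesenchymal genes had a median of 0.26 (0.0379, or 0.21), with SPARC lower (-1.04 ± 0.10) and CCN2 higher (1.68 ± 0.12). Leukocyte markers had a lower median (-0.58, 0.00728, or 0.249), with LAPTM5 at -2.39 ± 0.17. Leaving out sgITPR3 hypoxia replicate 1, the mesenchymal list (0.0581), the leukocyte markers (0.108) and the markers of hepatic, kidney and neural lines (-0.18, 0.0379 with it, 0.264 without) no longer passed. With an estimated correlation none of the 3 called lists kept its call without it (0.0744 for each).

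In hypoxia the guides were compared with sgCTRL under the same oxygen. SLC6A12 was at 44.8 ± 12.4 CPM in sgCTRL, 1.85 ± 0.876 in sgITPR3 (-4.51 ± 0.36, edgeR adjusted p = 1.75e-04) and 2.42 ± 0.750 in sgRELB (-4.21 ± 0.34, 7.79e-05). DKK4 fell by 3.14 with sgITPR3 and by 6.53 with sgRELB on the log2 scale, and IL24 changed by -2.72 ± 0.28 and -3.83 ± 0.30. COBLL1 (-3.82 ± 0.19) and LOX, a lysyl oxidase that crosslinks collagen (-2.50 ± 0.31), fell with sgITPR3, and KISS1 (-3.22 ± 0.37), VAT1L (-3.13 ± 0.16) and PTGS1 (-3.08 ± 0.20) fell with sgRELB. ADM2 fell by 3.02 with sgITPR3, or by 2.39 without sgITPR3 hypoxia replicate 1. RPS6KA6 had 207 counts with sgITPR3 and 321 with sgRELB against 4 (56.2, counting interval 21.6 to 208, and 68.6, 26.5 to 253). RNASE1 (3.71 ± 0.34), the mucin MUC13 (3.09 ± 0.21) and CTSS (3.07 ± 0.27) rose with sgITPR3, as did CST2, uncertain for its close paralogs (3.42, or 2.76 without that library). SPTLC3, of sphingolipid synthesis (3.86 ± 0.14), CDH11 (3.83 ± 0.28) and C1S (3.57 ± 0.18) rose with sgRELB. With sgITPR3, 2723 genes were called (1396 higher, 1327 lower; 987 at least 2-fold), and 6345 without the library (3145 higher, 3200 lower), 2666 of them shared. With sgRELB, 3016 were called (1535 higher, 1481 lower; 1258 at least 2-fold), and 8729 without it (4466 higher, 4263 lower), which included the 3016.

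NF-kB targets, the ATF4 response, immediate genes, endoplasmic reticulum stress genes and cholesterol synthesis were lower with both guides in hypoxia. NF-kB targets fell in 12 of 26 genes with sgITPR3 (13 adjusted over the list alone; median -0.70, camera adjusted p = 0.00246, or 0.0471 with an estimated correlation) and in 17 with sgRELB (19; -1.06, 3.22e-11, or 0.00767). With sgITPR3, ICAM1 fell (-0.98 ± 0.09) while PLAU (1.28 ± 0.16) and IL32 (2.24 ± 0.31) rose. The ATF4 and amino acid response fell in 11 and 14 of 24 (15 and 15; estimated-correlation p of 0.0382 and 0.0237): ATF3 was at 38.0 CPM in sgCTRL, 10.3 in sgITPR3 and 9.09 in sgRELB, and TRIB3 at 241, 65.9 and 71.1 CPM. Immediate genes fell in 14 of 24 with each guide (16 and 15; 0.0372 and 0.00869), with MYC at -0.90 ± 0.10 and -1.21 ± 0.10. Endoplasmic reticulum stress genes fell in 8 and 4 of 22 (8 and 6; 0.0372 and 0.0404), and cholesterol synthesis in 13 and 9 of 24 (15 and 13; 0.0372 and 0.0237). Hypoxia-inducible targets fell in 12 and 16 of 34 (14 and 18; 0.0372 and 0.00869), with VEGFA at 138 CPM in sgCTRL, 45.2 in sgITPR3 and 53.1 in sgRELB. With sgRELB the NF-kB family fell (9 of 19, 10 adjusted over the list alone; 0.0304), RELB included, as did histones (5 of 10, 5; 0.0304) and collagen-modifying enzymes (6 of 12, 6; 0.0304), and interferon-stimulated genes rose (10 of 29, 11; 0.0237). With sgITPR3, collagen-modifying enzymes (6 of 12, 6; 0.136 with an estimated correlation), fatty acid synthesis (7 of 15, 7; 0.38), led by SCD (-1.62 ± 0.15), and interferon-stimulated genes (6 of 29 higher, 10; 0.129) passed the preset test alone. Leukocyte markers were higher with sgITPR3 (median 0.73, camera adjusted p = 0.034, or 0.38 with an estimated correlation), with CORO1A at 0.98 ± 0.20. The sgITPR3 calls of the respiratory chain (0.51, camera adjusted p = 8.31e-04; -0.018 and 0.742 without sgITPR3 hypoxia replicate 1), interferon-stimulated genes (0.0618 without it), leukocyte markers (0.25 without it) and Wnt targets (0.034; 0.322 without it) rested on that library, and ribosomal proteins went from 0.42 to -0.25. With an estimated correlation, 3 of the 6 lists called with sgITPR3 and 1 of the 10 called with sgRELB, the hypoxia-inducible targets (0.0409), kept their calls without that library; NF-kB targets had 0.158 and 0.0772.

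How far the 2 guides changed the same genes was asked next. In normoxia they shared 660 higher and 467 lower calls, where independent lists would share 80.2 and 42.0, and 11 calls were opposite. Leaving out sgITPR3 hypoxia replicate 1, they shared 2402 higher and 2995 lower calls (787 and 1040 for independent lists, 205 opposite), so that lower calls were then the more numerous and the ratio to independent lists was smaller. In hypoxia they shared 775 higher and 774 lower calls (133 and 122 for independent lists, 27 opposite), or 2360 and 2400 without that library (843 and 819, 245 opposite). Genes lower with both in normoxia included DKK4, SORCS2, the adaptor PSTPIP1 (-2.74 ± 0.43 and -2.75 ± 0.43) and ZP1 (-2.40 ± 0.43 and -2.99 ± 0.46), and genes higher with both included RPS6KA6, CDH11 and PDGFRB (2.95 ± 0.34 with sgRELB). In hypoxia EFNA5 (-2.90 ± 0.22 and -2.60 ± 0.20) and ARHGAP9 (-2.59 ± 0.20 and -2.99 ± 0.20) were lower with both, and ZC4H2 (2.67 ± 0.19 and 3.13 ± 0.19) and ALPK2 (2.91 ± 0.35 and 2.90 ± 0.34) were higher. The log2 fold changes of the guides correlated across genes with r = 0.771 in normoxia and 0.682 in hypoxia, or 0.755 and 0.732 without that library. Both guides were set against the same sgCTRL libraries, and 20 simulations of unchanged groups against those controls gave a mean r of 0.569 and 0.506. The covariance was 0.36 against 0.0984 simulated in normoxia, a difference of 0.262, and 0.315 against 0.0588 in hypoxia, a difference of 0.256. The simulated spread came from the fit that holds sgITPR3 hypoxia replicate 1, which widened it. The simulated covariances, here and for the interactions below, may therefore be too high. In a fit chosen after the data had been seen, each guide was set against a different sgCTRL library, so that no library was shared. With sgITPR3 against replicate 1 and sgRELB against replicate 2, r was 0.544 in normoxia and 0.535 in hypoxia, and the covariance 0.338 and 0.287; the other way round, r was 0.524 and 0.591, and the covariance 0.332 and 0.306. With a lone control library per comparison fewer genes were called, and the guides shared 139 or 135 calls in the same direction in normoxia and 223 or 224 in hypoxia. The control libraries are duplicate wells of 1 population, so this does not separate an effect of both guides from a shift of the sgCTRL population.

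**Figure D4:**
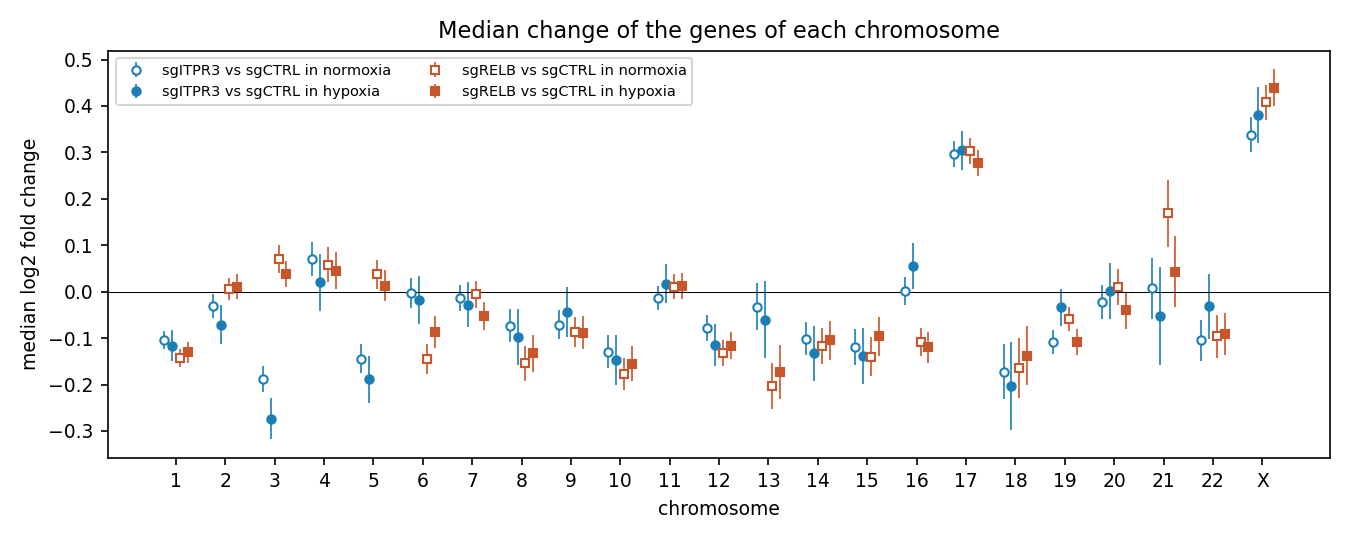
Median log2 fold change of the genes of each chromosome (horizontal axis) in the 4 comparisons of a guide with sgCTRL (vertical axis), with bars of 2 SD of medians after genes were shuffled between chromosomes. Chromosome X lies at 0.34 to 0.44 and chromosome 17 at 0.28 to 0.31 in all 4.

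Genes of chromosome X and of most of chromosome 17 were shifted upward with both guides. Over 9885 genes placed on the chromosomes, the 328 of chromosome X had a median log2 fold change of 0.34 in normoxia and 0.38 in hypoxia with sgITPR3, and of 0.41 and 0.44 with sgRELB. The 605 genes of chromosome 17 had medians of 0.30 and 0.31 with sgITPR3 and of 0.30 and 0.28 with sgRELB; its windows of 25 genes had medians of -0.039 to 0.28 up to position 21551678 and of 0.116 to 0.706 beyond. Over the whole of chromosome 3 the median was lower with sgITPR3 (-0.19 and -0.27), but its parts differed. The positions given here were chosen after the values had been seen. The first 3 windows were higher with both guides (0.035 to 0.299), and those from 38496340 to 58426127 were lower with both (-0.48 to -0.143 with sgITPR3, -0.349 to -0.141 with sgRELB). From 97822011 on, windows lay at -0.597 to -0.092 with sgITPR3 and at -0.02 to 0.349 with sgRELB. The median of chromosome 13 was lower with sgRELB (-0.20 and -0.17). That of chromosome 6, which holds ITPR3, was also lower with sgRELB (-0.145 and -0.087), as were those of several other chromosomes. How much of the lower ITPR3 level with sgRELB belongs to that shift was not tested. The SD of shuffled medians was 0.014 for chromosome 17 with sgRELB and 0.019 for chromosome X with sgRELB in normoxia.

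Whether a guide altered the response to hypoxia was tested as the difference between its response and that of sgCTRL. SLC6A12 rose in sgCTRL from 0.826 ± 0.313 to 44.8 ± 12.4 CPM, and stood at 0.868 ± 0.339 and 1.85 ± 0.876 CPM with sgITPR3, a difference of -4.52 ± 0.65 (edgeR adjusted p = 0.0255), and at 0.709 ± 0.0879 and 2.42 ± 0.750 CPM with sgRELB (-3.96 ± 0.66, 0.0402). EHD2 rose from 1.01 to 75.6 CPM in sgCTRL and from 5.33 to 54.4 CPM in sgITPR3 (-2.86 ± 0.27, edgeR adjusted p = 0.00833). ABCA1, a cholesterol transporter, rose from 0.984 to 14.99 CPM in sgCTRL and stood at 6.43 and 8.50 CPM in sgITPR3 and 5.14 and 9.13 CPM in sgRELB. The histone gene H2BC4 went from 18.6 to 11.2 CPM in sgCTRL and from 8.32 to 18.1 CPM in sgITPR3 (1.84 ± 0.22, edgeR adjusted p = 0.0169). FSTL4 fell from 16.2 to 4.74 CPM in sgCTRL and went from 4.17 to 6.11 CPM with sgRELB (2.33 ± 0.21, edgeR adjusted p = 0.00601). BIRC3 had a smaller response with both guides, -2.46 ± 0.41 (edgeR adjusted p = 0.0400) and -2.67 ± 0.44 (0.0405), as did NFKB2 and ATF3. In each interaction 83 genes were called, 8 higher and 75 lower for sgITPR3 and 16 higher and 67 lower for sgRELB. The 2 interactions shared 5 higher and 43 lower calls (0.00792 and 0.311 for independent lists), or 937 and 916 without sgITPR3 hypoxia replicate 1 (140 and 112), so the lean to lower calls does not hold without it and the ratio to independent lists is smaller. Without it r was 0.733 and the covariance 0.288; with all libraries they had r = 0.662 against a simulated 0.547 and a covariance of 0.249 against 0.158. With the sgCTRL libraries split between the guides, r was 0.278 or 0.319, the covariance 0.160 or 0.176, and no gene was called, in a fit with 4 residual degrees of freedom. Without sgITPR3 hypoxia replicate 1 there were 2603 calls for sgITPR3 (1360 higher, 1243 lower) and 3219 for sgRELB (1718 higher, 1501 lower), each with the 83, so the share of higher calls went from 9.64% to 52.2% and from 19.3% to 53.4%. With a replicate block, which takes replicate 1 and 2 as pairs across groups, 38 and 24 genes were called. SLC6A12, EHD2, ABCA1, H2BC4, ATF3 and NFKB2 for sgITPR3 and EHD2 and FSTL4 for sgRELB were among them. BIRC3 was not for either guide (edgeR adjusted p = 0.0737 and 0.0772), nor were SLC6A12 (0.0629), ABCA1 (0.0679), NFKB2 (0.0707) and ATF3 (0.0614) for sgRELB. At an unadjusted p under 0.05 the counts were 2315 and 1562, and when a library other than the 2 of sgITPR3 in hypoxia was left out the interactions called 0 to 10 and 0 to 22 genes. In simulated data with a known 2-fold difference, this fit recovered 16.4% of 67 genes for the sgITPR3 interaction, and 68.2% of 66 genes at 4-fold. The simulated spread came from the fit that holds sgITPR3 hypoxia replicate 1, so these rates need not hold for the data.

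**Figure D5:**
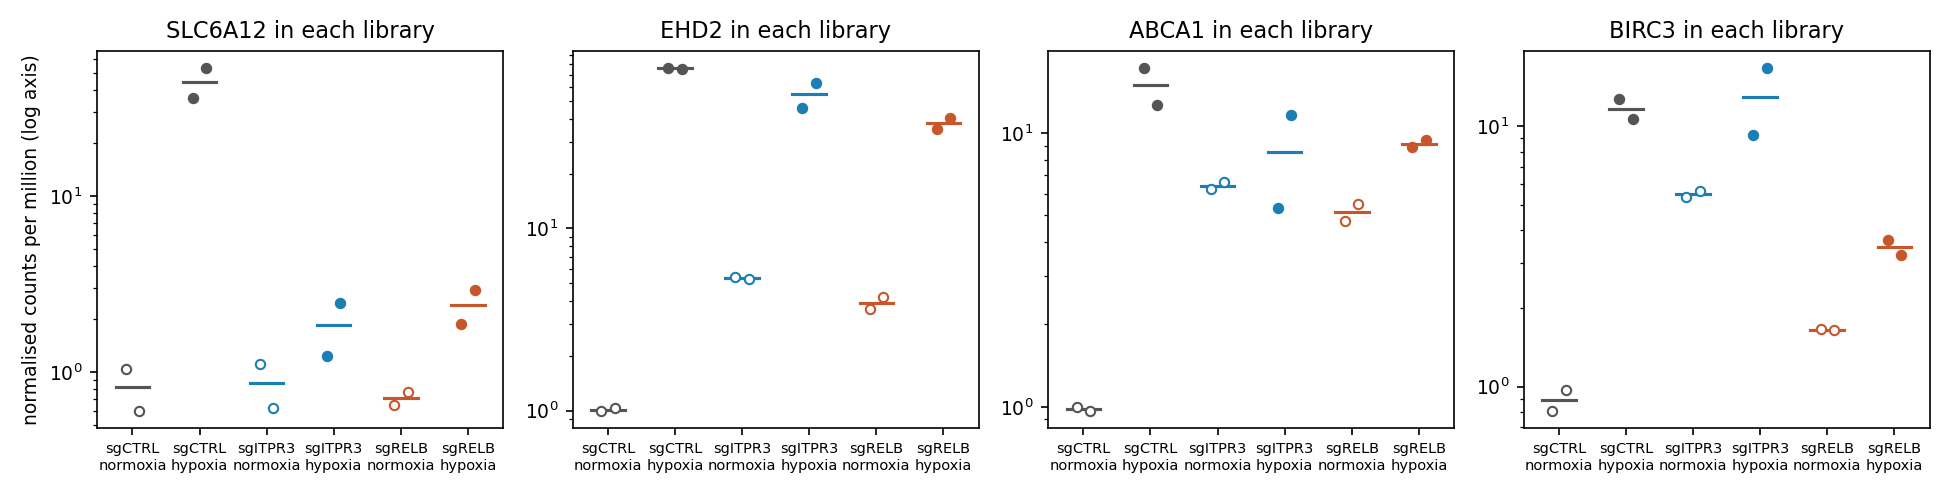
SLC6A12, EHD2, ABCA1 and BIRC3 in normalised counts per M (log axis) in the 6 groups, with each point a library and each line the mean of 2. In sgCTRL the means rise from 0.826 to 44.8, 1.01 to 75.6, 0.984 to 14.99 and 0.889 to 11.7, and in sgRELB from 0.709 to 2.42, 3.91 to 37.9, 5.14 to 9.13 and 1.66 to 3.43.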

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

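The tests of transcript length and of depth in the paragraph on the divergent library, and the test of the sgCTRL population, were chosen only after the result was seen. An interaction test, which takes the difference between the response to hypoxia with a guide and that with sgCTRL, picked the genes and lists of the next paragraphs. Each interaction called 83 genes.

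For sgITPR3 the largest positive differences among genes that met the naming rule (mean log2 CPM of at least 1) were in H2BC4 (1.84 ± 0.22), H2BC12 (1.52 ± 0.22), FSTL4 (1.38 ± 0.22), H2AC6 (1.28 ± 0.17) and VAT1L (1.25 ± 0.19). Under the same rule the largest negative ones were in SLC6A12 (-4.52 ± 0.65), ABCA1 (-3.48 ± 0.49), ITGA10 (-2.98 ± 0.45), EHD2 (-2.86 ± 0.27) and IL10RA (-2.62 ± 0.45). Some called genes outside that rule lay beyond EHD2, such as NEURL3 (-2.935). The histone genes fell in sgCTRL in hypoxia and not in sgITPR3, and SLC6A12 and EHD2 rose less with sgITPR3. Lists that kept the call with an estimated correlation were DNA replication (median 0.396, adjusted p = 0.0287), replication-dependent histones (1.048, 0.0106), NF-kB target genes (-0.624, 0.0106), endoplasmic reticulum stress (-0.524, 0.0143), immediate genes (-0.271, 0.0428) and mesenchymal genes (-0.539, 0.0287). Lists that passed only at the preset correlation, with the adjusted p from the estimated one, were glycolysis (0.3, 0.18), the nuclear-encoded respiratory chain (0.681, 0.467), mitochondrially encoded genes (-0.560, 0.422), fatty acid synthesis (-0.231, 0.547), mitosis (0.301, 0.0568), the NF-kB family (-0.147, 0.18), the ATF4 response (-0.269, 0.0843), cytosolic ribosomal proteins (0.848, 0.467) and leukocyte markers (0.938, 0.18). Without sgITPR3 hypoxia replicate 1 the medians were 0.171 for ribosomal proteins, 0.196 for the respiratory chain, -0.234 for mitochondrially encoded genes and -0.064 for fatty acid synthesis, so the size of those differences rests on that library, though all 15 lists still passed at the preset correlation in the same direction. With an estimated correlation, immediate genes lost the call without it (0.1), and mitosis (0.0428) and the ATF4 response (0.0428) gained it. Adjusted over the list alone, 10 of 26 NF-kB targets and 10 of 24 ATF4 genes had a smaller response, against 3 and 3 over all genes. With a replicate block FSTL4, VAT1L, ITGA10 and IL10RA were not called. The median difference in the size of the response was -0.180.

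For sgRELB the largest positive differences among genes that met the naming rule (mean log2 CPM of at least 1) were in PKHD1 (2.599 ± 0.45), FSTL4 (2.33 ± 0.21), CACNA1E (2.07), VAT1L (1.45) and HAS3 (1.42). Some called genes outside that rule had larger differences, such as IL2RA (3.884). Under the same rule the largest negative ones were in PRSS35 (-4.85, which rests on 4 counts in sgCTRL in normoxia), SLC6A12 (-3.96 ± 0.66), PTGS1 (-3.22), SDK2 (-3.17) and ABCA1 (-3.09). With a replicate block FSTL4 and SDK2 alone of these genes under the rule were called. Lists that kept the call with an estimated correlation were histones (median 0.639, adjusted p = 0.0315), the NF-kB family (-0.195, 0.0411), NF-kB target genes (-0.823, 0.00292), endoplasmic reticulum stress (-0.391, 0.0124), the ATF4 response (-0.395, 0.0454), immediate genes (-0.541, 0.0124) and mesenchymal genes (-0.406, 0.0178). Glycolysis (0.152, 0.269), DNA replication (0.238, 0.054), mitosis (0.201, 0.218) and leukocyte markers (0.665, 0.321) passed only at the preset correlation, the last of them not without sgITPR3 hypoxia replicate 1 (0.208). Without that library none of the 7 lists kept the call with an estimated correlation (0.0544 for NF-kB targets, 0.22 for the NF-kB family and 0.0653 for the others), and DNA replication gained it (0.0258). Adjusted over the list alone, 13 of 26 NF-kB targets had a smaller response, against 3 over all genes.

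The library sgITPR3 hypoxia replicate 1 differs from replicate 2 in a way that follows transcript length (Spearman rho -0.70, against at most 0.325 in size in the other pairs), but the bound set for this test, 3 times the others, was missed, so it cannot tell. Length is not the whole difference: the SD of the log2 difference was 0.520 after a correction for length, against 0.707 before and at most 0.112 elsewhere. Lower depth is excluded by a chi-square per gene, which allows for depth, of 126 against at most 3.27. Cells with sgCTRL or sgRELB are excluded by ITPR3 at a length-corrected 123 CPM, where the lowest library of those guides had 300. That test cannot exclude cells with a further guide against ITPR3, which could also have low ITPR3. Cells in normoxia are excluded by hypoxia-inducible genes (34 genes) at a median of 1.53 above normoxia, against 1.56 in replicate 2. Partial RNA degradation or another preparation effect could leave such a trend (rho -0.70); integrity values or a new library from the same RNA would tell.

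Both guides differ from sgCTRL in the same direction, and the 2 shared control libraries are not the whole reason: comparisons with no library in common correlated with r = 0.493 and 0.426. Genes of chromosomes 17 and X are not the whole reason, since 83.3% of shared calls in normoxia (939) lie on other chromosomes. Those hold 91.2% of tested genes, so chromosomes 17 and X have a larger share of the shared calls than of the genes. Shifts of other chromosomes that both guides share, such as chromosomes 10 and 18, were not covered by that count. An sgCTRL population that stands apart from the line could give the same pattern, as 317 genes were called between the 2 guides in normoxia, against 1589 and 2438 for each against sgCTRL (4565, against 7391 and 8195, without sgITPR3 hypoxia replicate 1, a much smaller contrast), and this test cannot tell it from an effect common to both edits. A further control population, or a second guide per gene, would tell.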

How the results depend on the processing

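Counts of called genes depend on sgITPR3 hypoxia replicate 1 and on how much spread each fit shares between groups, with 6 residual degrees of freedom and 1 guide per gene. The comparisons are given in the order hypoxia in sgCTRL, sgITPR3 and sgRELB, sgITPR3 against sgCTRL in normoxia and hypoxia, sgRELB against sgCTRL in normoxia and hypoxia, and the interactions of sgITPR3 and sgRELB. The cause of a change between settings was not tested unless stated. Of 163 named gene results, 43 lost their call and 3 gained one in fits of only the groups compared. At an adjusted p under 0.01, 23 lost their call, and 12 lost it with a replicate block. Calls were also lost when a library other than those of sgITPR3 in hypoxia was left out. None of 163 named gene results changed direction with a call in either fit. Results without a call did: RELB in hypoxia vs normoxia in sgITPR3 went from 0.21 (edgeR adjusted p = 0.387) to -0.067 (0.651) without sgITPR3 hypoxia replicate 1.

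The voom fit with library weights, chosen after seeing the data, gave the 2 libraries of sgITPR3 in hypoxia weights of 0.0586 and 0.0746 and the others 1.52 to 2.13, and called 9905, 729, 9037, 7696, 360, 8024, 8244, 68 and 2704 genes. Fits of only the groups compared called 9674, 0, 9110, 7695, 0, 8066, 8401, 0 and 2997. The comparisons with 0 calls in edgeR hold the divergent library, had 2314, 1931 and 1398 genes at an unadjusted p under 0.05, and called 3912, 3370 and 357 genes with DESeq2 and 3498, 2674 and 77 with voom on all libraries. At an adjusted p under 0.01 the counts were 2758, 1573, 1664, 629, 953, 1035, 1478, 7 and 12. An offset for transcript length, chosen after seeing the data, called 3120 (48.9% higher) for sgITPR3 and 4021 for sgRELB against sgCTRL in normoxia, and 460 (29.8% higher) and 399 (33.3% higher) in the interactions. DESeq2 called 357 (24.6% higher) and 334 (31.7% higher) genes in the interactions, and 51.1% of its calls were higher for sgITPR3 in normoxia. A replicate block called 38 and 24 in the interactions; whether replicate numbers pair libraries across groups is left open, because the median correlation of their deviations was 0.039 and 7 of 15 pairs of groups were over 0.1. Among sgITPR3 and sgRELB in normoxia and sgCTRL and sgRELB in hypoxia it was 0.129 to 0.367, and elsewhere it went down to -0.422. DESeq2 size factors and other filters left counts closer to the first ones, such as 4863, 4314 and 4455 for hypoxia in sgCTRL. Of 297 list tests 142 passed, and 53 with an estimated correlation, or 44 without sgITPR3 hypoxia replicate 1, with 29 in both. The list cytosolic ribosomal proteins in hypoxia vs normoxia in sgITPR3 changed direction without sgITPR3 hypoxia replicate 1, to -0.186 (limma camera adjusted p = 4.26e-04), and had 1.01 without replicate 2. The list cytosolic ribosomal proteins in sgITPR3 vs sgCTRL in hypoxia went to -0.253 (1.5e-07) and to 0.935.

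With each library left out in turn, the counts ranged over 2663 to 10036, 1225 to 10535, 1401 to 9351, 448 to 7391, 683 to 10695, 820 to 8199, 1255 to 8731, 0 to 9174 and 0 to 3219. The top of each range came from leaving out 1 of the 2 libraries of sgITPR3 in hypoxia, and the low ends from leaving out a library of the groups compared. Counts moved more than 1.5 times in at least 1 comparison for every library left out. Where an interaction called 0 genes in edgeR, 1384 to 1558 (sgITPR3) and 1076 to 1170 (sgRELB) genes had an unadjusted p under 0.05. List tests passed in 134 to 152 cases. Genes shared by the 3 hypoxia responses numbered 953 to 5962 (1891 with all libraries), and those shared by the guides 310 to 5399 in normoxia (1127) and 461 to 4760 in hypoxia (1549). With each guide against a different sgCTRL library, chosen after seeing the data, the guides shared 139 or 135 genes in normoxia and 223 or 224 in hypoxia, in a fit with 4 residual degrees of freedom. The difference in response size ranged from -0.304 to -0.087 for sgITPR3 and from -0.149 to -0.041 for sgRELB, and for sgRELB it passed without sgITPR3 hypoxia replicate 1 (limma fry, not exact, p = 3.97e-04) and without sgITPR3 normoxia replicate 1 (0.0437).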

Other observations

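BMP4, a secreted BMP ligand, rose in hypoxia in sgCTRL (1.56 ± 0.13, edgeR adjusted p = 4.02e-05) and was higher with sgRELB in normoxia (1.95 ± 0.13) and hypoxia (1.34 ± 0.12) and with sgITPR3 in normoxia (1.02 ± 0.12). The receptor EPHB3 was higher with sgITPR3 (0.72 ± 0.10) and sgRELB (1.37 ± 0.10) in normoxia, and DKK4 was lower in each of these comparisons. TCF7, a transcription factor of the Wnt pathway, fell in hypoxia in all 3 populations (-0.96 ± 0.09, -0.91 ± 0.09 and -0.83 ± 0.09). As a list, Wnt targets and colon stem cell genes (22 genes) passed for sgITPR3 in normoxia (-0.028, limma camera adjusted p = 0.0439, or 0.511 with an estimated correlation) and hypoxia (-0.042, 0.034, or 0.531). Without sgITPR3 hypoxia replicate 1 the call for sgITPR3 in hypoxia was lost (0.322), and the list passed for hypoxia in sgCTRL (-0.078, 0.0221), sgITPR3 in normoxia (-0.045, 0.00143) and sgRELB in normoxia (-0.103, 0.0176).

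VIL1 and the transcription factor HNF4A were higher with sgITPR3 in normoxia (2.95 ± 0.19 and 2.44 ± 0.18) and hypoxia (2.42 ± 0.18 and 1.62 ± 0.17), and the splicing regulator ESRP1 was lower with both guides in hypoxia (-1.54 ± 0.13 and -1.66 ± 0.13). Colon differentiation genes were lower with sgRELB in normoxia (3 of 14, 3 adjusted over the list alone; limma camera adjusted p = 0.0379, or 0.21 with an estimated correlation) and hypoxia (6 of 14, 7; 0.0192, or 0.0814). Apoptosis regulators were lower with sgRELB in hypoxia (9 of 25, 10 adjusted over the list alone; 0.0163, or 0.0854), with PMAIP1 at -0.91 ± 0.11. The metallothionein MT1X rose in hypoxia in sgCTRL (1.98 ± 0.32) and was lower with sgRELB in hypoxia (-2.33 ± 0.33). Markers of hepatic, kidney and neural lines rose in hypoxia in sgCTRL (3 of 6, 3 adjusted over the list alone; 0.0259, or 0.198) and were lower with sgRELB in hypoxia (3 of 6, 3; 0.00104, or 0.0814), with PAX8 at 1.83 and -1.65; without sgITPR3 hypoxia replicate 1 the first of these did not pass (0.0761) and the second did (0.0333). The growth factor gene GDF15 was lower with both guides in hypoxia (-1.85 ± 0.15 and -1.65 ± 0.15), though p53 targets passed in no comparison (23 genes, medians -0.133 to 0.277, smallest adjusted p = 0.0932), and neither did lipid droplet genes (11 genes, -0.214 to 0.067, 0.285). In the fit without sgITPR3 hypoxia replicate 1, p53 targets passed for hypoxia in sgCTRL (0.0491), and lipid droplet genes for sgITPR3 in hypoxia (0.0332).

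The 2 targeting guides were compared with each other after the data had been seen. In normoxia 317 genes differed (110 higher and 207 lower with sgRELB), and in hypoxia 957 (482 and 475). Leaving out sgITPR3 hypoxia replicate 1, there were 4565 (2330 higher and 2235 lower) and 4077 (2028 and 2049), so the excess of lower calls in normoxia did not hold.

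The test with alternate genes was chosen after a first test of copy number was set aside, because whole windows also correlated when genes were shuffled (0.581). Chromosome X and parts of others, such as chromosomes 3 and 17, were shifted between the guides and sgCTRL. On chromosome X 85.1 to 92.4% of the 328 genes were above 0, so a few strongly changed genes are excluded there. Correction for GC content and length left medians of 0.322 to 0.445 on chromosomes X and 17, which excludes that bias. Windows of 25 genes kept their shift between alternate genes and oxygen levels, with r = 0.711 for sgRELB and 0.605 for sgITPR3, against 0.135 to 0.230 for the 3 pairs of hypoxia responses and at most 0.201 and 0.160 in 200 shuffles for each guide. This could come from copy number differences between the cell populations (r = 0.711), although regional regulation would leave the same trace, and DNA copy number of the 3 populations would tell.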
